A study of Mus musculus with 4 samples.

How the data were processed

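Poly(A) RNA of isolated mouse glomeruli was sequenced in 4 libraries, 2 control and 2 labelled as podocyte-specific knockout of Hdac1 and Hdac2, at 3 weeks of age and with 2 mice per library, per the labels and the series' design text. The submitters' processing notes name fastp 0.20, STAR 2.7.9, featureCounts 2.0.0, DESeq2 1.30.1 and the genome build GRCm38.p6, with no role or order given for the tools. The authors deposited 1 table of TPM values for 22809 Ensembl genes in 4 columns, each of which sums to 1000000, and all 4 columns were matched to samples by name. The filter that chose the listed genes, the gene annotation and the strand setting are not given in the sources used here. Replicates are separate pools of mice, so their spread includes that between pools.

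TPM keeps no depth of its own, but the depth could be recovered. Each TPM value was multiplied by the union of the gene's exon lengths in GENCODE M21, an annotation of GRCm38. For 22176 genes (97.2%) the products were whole multiples of 1 step per library, for 100% of their values, within a relative tolerance of 1e-06. These whole reads numbered 15808117, 12876939, 17476365 and 20943138 in control replicates 1 and 2 and knockout replicates 1 and 2. Every one of these genes had at least 6 reads in at least 1 library. Symbols were found for 22762 genes.

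The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on log2(TPM + 1) over all 4 libraries with no covariate. Genes entered with a mean of at least 1 TPM, which kept 18612 and left out 4197. P values were adjusted by the Benjamini-Hochberg method and called below 0.05. Fold changes are knockout-labelled against control on the log2(TPM + 1) scale, which understates the change of low genes, and every adjusted p for a gene is from limma. An exact permutation test of 2 against 2 cannot go below 0.333 two-sided and was not used. Of the 4 libraries, 2 residual degrees of freedom remain, with moderation of the variances across genes.

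Fixed before the data were examined were 30 gene lists of glomerular and tubular cell types, immune and blood cells, cell cycle, stress, injury, matrix, metabolism, HDAC genes and their complexes, and sex-linked genes. Lists with at least 5 tested members, 29 in all, were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists. The germline list had 2 tested members and its values are given. The count of members past the threshold is given over all genes tested and adjusted over the list alone. The genes named were also fixed by rule. They were Hdac1 and Hdac2, the 12 genes with the largest change in each direction among those past the threshold with no overlap between the groups, and up to 4 members of each list with the smallest p. Predicted, clone-named and mitochondrial genes were left out of the 12. Where fewer than 5 genes passed in a direction, as happened in both, the 12 with the smallest unadjusted p, no overlap and a log2 fold change of at least 1 in size were taken instead and are given as values. Some genes that the rule names are not reported here. Gm22513 is named as the 1 gene past the threshold. Genes named outside the rule are said to have been chosen after their values were seen.

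Numbers were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. The test was checked on simulated reads drawn from the real genes' means and library sizes with a dispersion of 0.02, in 5 runs with 200 changed genes each, for the comparison of knockout-labelled against control. Over an average of 18181 tested genes, limma on log2(TPM + 1) called 26.9% of the 2-fold changes, 97.0% of the 4-fold changes and 99.4% of the 8-fold changes. It made 76 false calls, beside 90, 325 and 328 calls of the genes changed 2-fold, 4-fold and 8-fold, and 0 of 145 list tests were called. The simulated genes varied independently, so the list count cannot test camera where members move together. The real lists had estimated correlations up to 0.97. Voom on the recovered reads called 77.0%, 97.6% and 99.4%, with 44 false calls. The real libraries of a group differed by a median of 0.39 log2 units in size between the controls and 0.20 between the knockout-labelled libraries. The simulation gave all genes and libraries the same dispersion, so it did not hold the wider spread between the controls. Its shares of changes called can therefore be too high for these data.

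Each result was also computed with pseudocounts of 0.1 and 5, no filter, a mean of at least 5 TPM, median-ratio scaling, quantile normalization, limma without trend, the replicate number as a block, a minimum log2 fold change of 1, and each library left out in turn, where the lone library of a group is assumed to vary like those of the other group. The planned count models and their normalization and filter alternatives were not run, although whole reads were recovered, since the deposited unit is TPM. In their place limma's voom was run on the recovered reads, with the total of the reads, with median-ratio factors and with the replicate block, and an adjusted p under 0.1 was tried, all chosen after seeing the data. Overlap of exons was taken from GENCODE M21 on either strand.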

Results

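RNA sequencing of poly(A) RNA measured gene expression in glomeruli, the filtering units of the kidney, freshly isolated from mice at 3 weeks of age. There were 2 control libraries and 2 libraries labelled as knockout of Hdac1 and Hdac2 in podocytes, the epithelial cells that wrap the glomerular capillaries. Each library pooled the glomeruli of 2 mice, and per the series' design text there were 2 independent experiments. HDAC1 and HDAC2 are closely related histone deacetylases that act in corepressor complexes. The 1 comparison of the design was the knockout-labelled against the control libraries, and it asks which glomerular transcripts differ when podocytes lack both enzymes. Values were TPM, read counts divided by gene length and scaled to the same total in each library. The whole reads recovered from them numbered 15808117 and 12876939 in the control libraries and 17476365 and 20943138 in the knockout-labelled libraries. Mitochondrially encoded genes held between 38.7% and 46.5% of the TPM of a library.

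The targeted genes were read first. Hdac1 (chromosome 4, 129516104 to 129542713 in GRCm38) was at 18.9 ± 0.523 TPM in the controls and 22.7 ± 0.349 TPM in the knockout-labelled libraries (SD, n = 2 each), a log2 fold change of 0.25 (SE 0.17, adjusted p = 0.512 by limma). Hdac2 (chromosome 10, 36974544 to 37001889) was at 22.2 ± 2.76 and 22.2 ± 1.87 TPM, a log2 fold change of 0.01 (SE 0.19, adjusted p = 0.991). Neither transcript was lower in the knockout-labelled libraries, so the target transcripts do not check the labels. Whole glomeruli also hold endothelial, mesangial and parietal cells, which the deletion leaves out by design. The libraries held tubular transcripts too. The fixed proximal tubule list summed to 52813 and 13979 TPM in control replicates 1 and 2 and to 7521 and 8928 TPM in knockout replicates 1 and 2. The podocyte list summed to 2227, 2670, 1493 and 1971 TPM in the same order. The values are per gene, so a transcript lacking some exons is still counted. The direction of every difference given here rests on the labels.

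Among 18612 genes tested, 1 gene passed the adjusted threshold. Gm22513, a 164-base snRNA gene (chromosome 12, 54696782 to 54696945, plus strand), fell from 702 ± 70.6 TPM in the controls to 4.80 ± 1.64 TPM in the knockout-labelled libraries (SD, n = 2 each; log2 fold change -6.95, SE 0.24, adjusted p = 0.00688). Its value is uncertain as a measure of 1 locus, because 16 other snRNA genes of the same length differ from it by at most 10 bases, 6 of them on chromosome 12, and reads from near-identical copies can be assigned to any of them. The closest copies, Rnu1a1 among them, differ by 1 base. The libraries were made from poly(A) RNA, and how an snRNA came to be counted in them was not tested. The call was lost without control replicate 1 (adjusted p = 0.0663), with quantile normalization (0.0749) and with limma without trend (0.0609), and the adjusted p of Gm22513 was between 1.47e-06 and 0.0822 over the settings tried. No gene was called higher by limma, although 2497 genes were higher and 831 lower at an unadjusted p under 0.05, and voom on the recovered reads called 0 in either direction. The excess upward depended on the scaling. At that unadjusted threshold, 1775 genes were higher and 1338 lower by limma with median-ratio scaling, and 2080 and 1657 with quantile normalization. At an adjusted p under 0.1, a threshold chosen after the values were seen, 130 genes were higher and 46 lower. Without control replicate 2 the counts at the 0.05 threshold were 1558 higher and 522 lower. Of the tested genes, 50.9% had both knockout-labelled values on the same side of both control values, 6822 above and 2658 below in TPM as deposited. Chance gives 33.3% on average, for 1 of 3 possible splits. Genes move together across the libraries, so a share above 33.3% is not by itself evidence of a difference.

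The genes with the smallest p in each direction did not pass the threshold and are given as values. Higher in both knockout-labelled libraries were C1qa and C1qb, subunits of the complement component C1q made by macrophages. C1qa was at 13.8 ± 5.22 TPM in the controls and 105 ± 10.7 TPM in the knockout-labelled libraries (SD, n = 2 each; log2 fold change 2.89, SE 0.28), and C1qb was at 15.7 ± 6.04 and 112 ± 5.09 TPM (2.80, SE 0.28). The log2 fold change was 1.85 (SE 0.16) for Il34, a ligand of the macrophage growth factor receptor, 1.82 (SE 0.17) for F3, the tissue factor that starts coagulation, and 1.77 (SE 0.17) for F2rl1, a protease-activated receptor. Cpe, which trims peptide hormones, was 4.71-fold higher, Ptgds, a prostaglandin D synthase, 3.57-fold, Isg15, an interferon-induced ubiquitin-like protein, 5.15-fold, Tapbp, which loads peptides on MHC class I, 3.32-fold, Hist1h2bl 3.38-fold and Vat1 3.74-fold. Exons of Tapbp share 29.0% of their bases with other genes. Mir6358 was at 0 reads in both controls and at 7 and 8 reads in the knockout-labelled libraries. Among the lower genes, Miox, the myo-inositol oxygenase of the proximal tubule, was at 852 ± 42.2 TPM in the controls and 162 ± 62.8 TPM in the knockout-labelled libraries (log2 fold change -2.44, SE 0.30), and G6pc, the glucose-6-phosphatase that releases glucose, at 445 ± 68.1 and 107 ± 12.6 TPM (-2.04, SE 0.20). Acmsd, an enzyme of tryptophan breakdown, was 5.34-fold lower, the adenylate kinase Ak4 5.31-fold, the carboxylesterase Ces1d 3.89-fold, the glycerol kinase Gk 2.93-fold, the fucosyltransferase Fut9 2.85-fold, Cyp2j11 3.74-fold, Slc10a5 3.14-fold, Slc16a4 3.02-fold, Pm20d1 2.98-fold and Tmem64 2.90-fold. All 24 had an adjusted p of 0.0928.

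**Figure D1:**
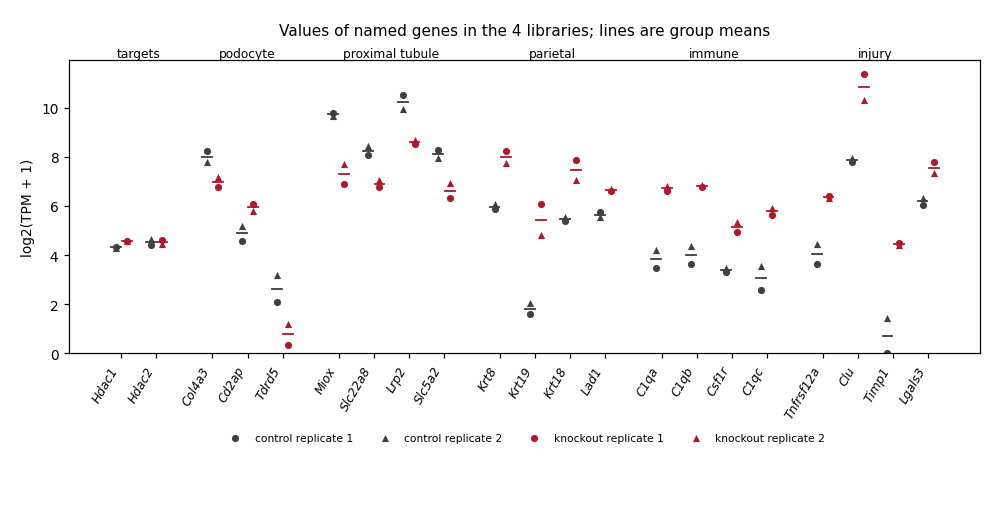
Each point is 1 library, with log2(TPM + 1) on the vertical axis and genes on the horizontal axis; circles are replicate 1, triangles replicate 2, and lines the group means. Hdac1 and Hdac2 lie at the same level in both groups within 0.25 log2 units, while the 4 Miox values run from 118 TPM to 882 TPM, the knockout-labelled ones lowest.

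For groups of genes, 22 of 29 lists fixed before the data were examined passed camera with a preset correlation of 0.01, 14 upward and 8 downward. No list passed with an estimated correlation (lowest adjusted p = 0.550 with an estimated correlation) or by fry (lowest adjusted p = 0.125). Across all tested genes the median log2 fold change was 0.17 as deposited and -0.03 after median-ratio scaling, a shift of 0.20, so the medians of lists are given relative to the median of all tested genes. Apart from the snRNA gene, 0 genes passed over all genes tested, so each list's count over all genes tested was 0.

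Podocyte genes fell as a group, with a median of -0.63 relative to all genes over 36 members (SD of the log2 fold changes 0.85, camera adjusted p = 1.32e-06; adjusted p = 0.550 with an estimated correlation). Col4a3, a collagen IV chain of the glomerular basement membrane, was at 259 ± 55.9 TPM in the controls and 127 ± 25.9 TPM in the knockout-labelled libraries (SD, n = 2 each; log2 fold change -1.02, SE 0.24, adjusted p = 0.131 by limma), and Tdrd5 was 3.63-fold lower. Cd2ap, the adaptor that binds nephrin, was 2.08-fold higher. Of the 36 members, 13 were lower in both knockout-labelled libraries than in both controls and 4 were higher, and 0 passed adjusted over the list alone. The median ranged from -0.84 without control replicate 1 to -0.39 without knockout replicate 1. Glomerular endothelial genes also fell by camera, with a median of -0.34 over 22 members (adjusted p = 0.0102; adjusted p = 0.650 with an estimated correlation), 0 of them adjusted over the list alone. That call was lost without control replicate 2 (adjusted p = 0.545, median 0.07) and without knockout replicate 1 (adjusted p = 0.794, median -0.02), while the median was -0.79 without control replicate 1 and -0.72 without knockout replicate 2. It was also lost with quantile normalization (0.0741), and the adjusted p was between 9.65e-07 and 0.794 over the settings tried. Ehd3, a glomerular endothelial marker, was at 63.4 and 149 TPM in the controls and 34.7 and 76.6 TPM in the knockout-labelled libraries, and Flt1, a VEGF receptor, at 14.4, 32.4, 10.1 and 19.0 TPM in the same order. Lpl, the lipoprotein lipase, was 3.61-fold lower and Fabp4 1.58-fold higher. Replicate 2 of each group held more endothelial transcripts than replicate 1, by a median of 1.09 log2 units in the controls and 0.96 in the knockout-labelled libraries. Mesangial and vascular smooth muscle genes did not pass (median -0.08 relative to all genes and 0.09 as deposited over 18 members, adjusted p = 0.434; 0.783 with an estimated correlation), and the relative median was 0.09 without control replicate 2, 0.04 without knockout replicate 1, -0.22 without control replicate 1 and -0.24 without knockout replicate 2. Their log2 fold changes were 0.58 (SE 0.16) for Ren1, which encodes renin, 0.58 (SE 0.21) for Cspg4, -0.50 (SE 0.20) for Myh11 and -1.18 (SE 0.47) for Sfrp2.

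Genes of the tubule fell. Proximal tubule genes had a median of -1.60 over 24 members (SD 0.67, camera adjusted p = 1.38e-18; adjusted p = 0.550 with an estimated correlation), and all 24 log2 fold changes were negative, 15 of them past the threshold adjusted over the list alone. Lrp2, the endocytic receptor megalin, was at 1225 ± 322 TPM in the controls and 389 ± 36.7 TPM in the knockout-labelled libraries (SD, n = 2 each), Slc5a2, the glucose cotransporter SGLT2, at 279 ± 45.5 and 99.8 ± 28.3 TPM, and Slc22a8, an organic anion transporter, at 306 ± 55.8 and 120 ± 17.5 TPM. The median was -0.79 without control replicate 1, the library with the highest summed TPM of the list, 52813 against 13979 in control replicate 2 and 7521 and 8928 in the knockout-labelled libraries. Kap, chosen after its values were seen, held 31062 TPM of that sum in control replicate 1 and 987 TPM in control replicate 2. Over the list, control replicate 2 differed from control replicate 1 by a median of -0.57 log2 units. Genes of the loop, distal tubule and collecting duct had a median of -0.53 over 17 members (adjusted p = 7.28e-05; adjusted p = 0.550 with an estimated correlation), or -0.32 without control replicate 1 and -0.23 without knockout replicate 2, and 4 passed adjusted over the list alone. These were the anion exchanger gene Slc4a1 (4.23-fold lower), the parvalbumin gene Pvalb (4.05-fold), the calbindin gene Calb1 (2.97-fold) and the pendrin gene Slc26a4 (2.01-fold).

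Nuclear genes of oxidative phosphorylation fell with a median of -0.64 over 28 members (SD 0.15, camera adjusted p = 1.89e-14; adjusted p = 0.550 with an estimated correlation). Of these, 27 were lower in both knockout-labelled libraries than in both controls and 0 passed adjusted over the list alone; the median was -0.40 without control replicate 1. Ndufa4 was 1.63-fold lower, Ndufs1 1.66-fold, Uqcrfs1 1.57-fold and Sdhb 1.52-fold. Mitochondrially encoded genes passed by a small margin (median -0.33 over 13 members, adjusted p = 0.0140; adjusted p = 0.584 with an estimated correlation), 0 of them adjusted over the list alone, and the call was lost without control replicate 2 (0.0983) and without knockout replicate 2 (0.540, median -0.14), and with quantile normalization (0.237). The log2 fold changes were -0.48 (SE 0.22) for mt-Co3, -0.26 (SE 0.15) for mt-Co2, -0.36 (SE 0.38) for mt-Atp6 and 0.37 (SE 0.53) for mt-Atp8. These values are uncertain, because mitochondrial genes have near-identical nuclear copies that can share reads, and mt-Atp8 shares 21.1% of its bases with mt-Atp6. Cholesterol synthesis genes fell with a median of -0.45 over 18 members (adjusted p = 0.000232; adjusted p = 0.550 with an estimated correlation), -0.24 without control replicate 1 and -0.69 without control replicate 2, 0 of them adjusted over the list alone. Insig1 was 1.64-fold lower, Nsdhl 1.54-fold, Hmgcs1 1.90-fold and Cyp51 3.17-fold. Cyp51 was at 117 and 33.1 TPM in control replicates 1 and 2 and at 20.8 and 17.3 TPM in the knockout-labelled libraries. Heat shock and unfolded protein response genes passed downward (median -0.35 over 18 members, adjusted p = 0.0272; adjusted p = 0.550 with an estimated correlation) but not without control replicate 1 (0.878, median -0.01) or knockout replicate 2 (0.252, median -0.19), and the median was -0.70 without control replicate 2. The call was also lost with no filter (0.0646), median-ratio scaling (0.118), quantile normalization (0.293) and voom with median-ratio factors (0.0562), in a range from 0.000160 to 0.878 over the settings tried. The chaperone gene Hsph1 was 2.39-fold lower and Herpud1 2.11-fold lower, while Hspb1 was 2.33-fold higher and the asparagine synthetase gene Asns 2.30-fold higher; these 4 passed adjusted over the list alone.

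Genes of immune cells rose. Their median was 2.23 over 18 members (SD 0.77, camera adjusted p = 1.70e-11; adjusted p = 0.550 with an estimated correlation), and 17 were past the threshold adjusted over the list alone. Csf1r, the macrophage growth factor receptor, was at 9.44 ± 0.941 TPM in the controls and 34.8 ± 7.08 TPM in the knockout-labelled libraries (SD, n = 2 each), and C1qc was 6.50-fold higher. Their summed TPM was 173 and 539 in the controls and 2273 and 2500 in the knockout-labelled libraries. Interferon response genes had a median of 1.62 over 24 members (adjusted p = 1.70e-11; adjusted p = 0.550 with an estimated correlation), 23 of them past the threshold adjusted over the list alone. Irf7, a transcription factor of the interferon response, was 5.90-fold higher, Oas1a 3.49-fold and Bst2, which tethers budding virus, 3.46-fold. Secreted factors associated with senescence had a median of 1.81 over 27 members (adjusted p = 1.06e-06; adjusted p = 0.550 with an estimated correlation), with 20 past the threshold adjusted over the list alone. Gdf15, a stress-induced cytokine also in the p53 list, was 4.62-fold higher, the cytokine Lif 7.54-fold and the chemokine Ccl7 6.98-fold, from control values of 0.137 and 1.93 TPM for Lif and 0 and 1.63 TPM for Ccl7.

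Kidney injury genes rose with a median of 2.87 over 20 members (SD 1.64, camera adjusted p = 4.14e-09; adjusted p = 0.550 with an estimated correlation), and 18 were past the threshold adjusted over the list alone. Clu, which encodes clusterin, was at 231 ± 19.7 TPM in the controls and 1970 ± 1006 TPM in the knockout-labelled libraries (SD, n = 2 each). Tnfrsf12a, the TWEAK receptor gene, was 4.97-fold higher, the galectin gene Lgals3 2.59-fold and the protease inhibitor gene Timp1 13.3-fold. The control values of Timp1 were 0 and 1.68 TPM. Parietal epithelial genes, of the cells that line Bowman's capsule, rose with a median of 1.26 over 14 members (adjusted p = 8.37e-07; adjusted p = 0.550 with an estimated correlation), 12 of them past the threshold adjusted over the list alone. The keratins Krt8, Krt18 and Krt19 were 4.04-fold, 3.98-fold and 12.4-fold higher, and Lad1 2.02-fold. Cd44 is in both the parietal and the injury list, and pooled libraries do not show which cells made these transcripts.

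**Figure D2:**
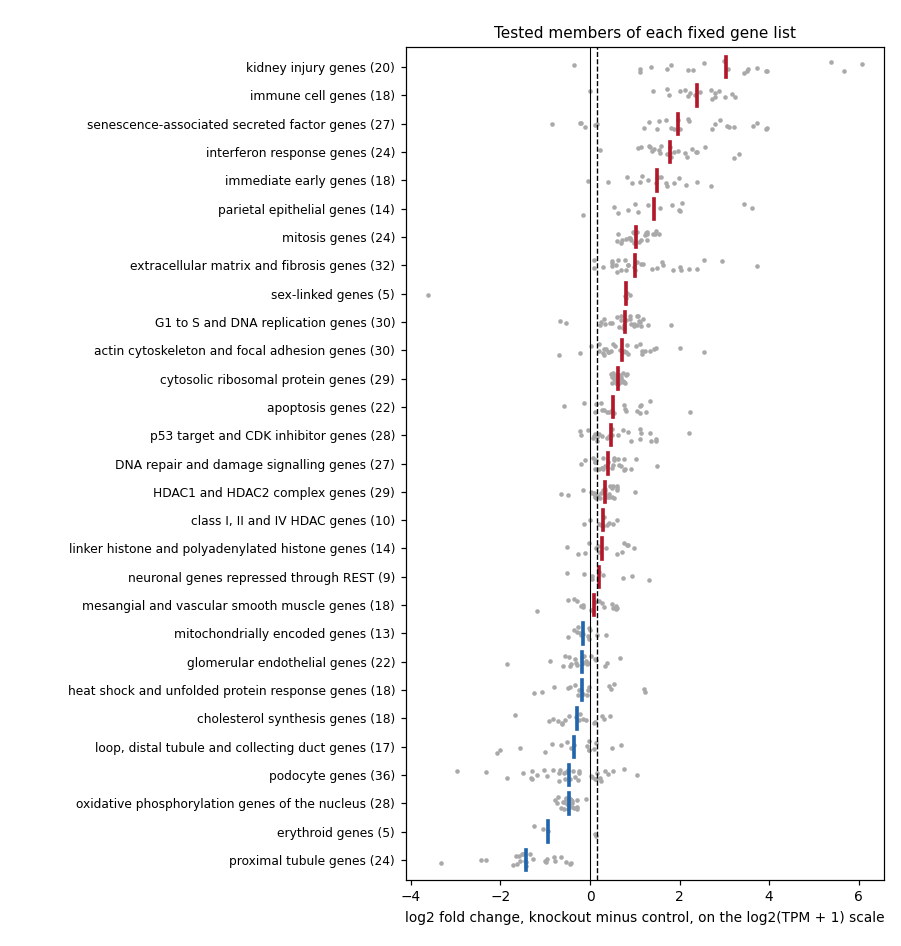
Each grey point is 1 tested member of a fixed gene list, with the log2 fold change on the log2(TPM + 1) scale on the horizontal axis and the number of members in brackets; bars are list medians, red above 0 and blue below, and the dashed line is the median of all tested genes at 0.17. Kidney injury genes (median 3.03) and proximal tubule genes (median -1.43) stand at the ends; median-ratio scaling moves the median of all genes down by 0.20, and the mesangial median goes from 0.09 to -0.12.

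Genes of proliferation rose. All 24 mitosis genes were higher in both knockout-labelled libraries than in both controls, with a median of 0.87 (SD 0.28, camera adjusted p = 6.91e-10; adjusted p = 0.550 with an estimated correlation), and 17 were past the threshold adjusted over the list alone. Top2a, the topoisomerase of dividing cells, was at 6.42 ± 2.80 TPM in the controls and 18.8 ± 2.14 TPM in the knockout-labelled libraries (SD, n = 2 each), Ccnb2 was 2.41-fold higher, Bub1b 2.80-fold and Tpx2 2.66-fold. The genes of the G1 to S transition and DNA replication had a median of 0.61 over 30 members (adjusted p = 2.23e-06; adjusted p = 0.550 with an estimated correlation), 7 past the threshold adjusted over the list alone. Rrm2, a ribonucleotide reductase subunit, was 2.17-fold higher, Uhrf1 3.48-fold, Ccna2 2.45-fold and Mcm4 2.10-fold. DNA repair and damage signalling genes had a median of 0.23 over 27 members (adjusted p = 0.00360; adjusted p = 0.584 with an estimated correlation), 0 of them adjusted over the list alone. The call was lost with a mean of at least 5 TPM (0.125, median 0.14), and the adjusted p was between 0.00154 and 0.125 over the settings tried. H2afx was 2.03-fold higher, and Rad51b, Brca2 and Rad54l were at 0.747, 1.67 and 1.06 TPM in the controls and 3.85, 3.47 and 2.46 TPM in the knockout-labelled libraries. The p53 targets and CDK inhibitors had a median of 0.29 over 28 members (adjusted p = 0.00309; adjusted p = 0.550 with an estimated correlation), and the 4 past the threshold adjusted over the list alone were Gdf15, Btg2 (2.78-fold higher), the death effector gene Pmaip1 (2.21-fold) and Plk3 (2.79-fold). Apoptosis genes had a median of 0.35 over 22 members (adjusted p = 0.000853; adjusted p = 0.550 with an estimated correlation), 0.58 without control replicate 2. The 4 past the threshold adjusted over the list alone were Pmaip1, Bak1 (2.18-fold higher, with 25.5% of its exon bases in Ggnbp1) and Bmf (2.38-fold), which promote cell death, and Birc3 (4.69-fold), which restrains it.

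Immediate early genes, transcribed within minutes of a stimulus, had a median of 1.34 over 18 members (camera adjusted p = 4.79e-09; adjusted p = 0.550 with an estimated correlation), with 16 past the threshold adjusted over the list alone. Junb was at 25.4 ± 7.06 TPM in the controls and 113 ± 7.39 TPM in the knockout-labelled libraries (SD, n = 2 each), Fos was 3.30-fold higher, Egr1 3.25-fold and Zfp36 2.86-fold. Cytosolic ribosomal protein genes rose by a small and even amount, with a median of 0.47 over 29 members (SD 0.10, adjusted p = 1.40e-08; adjusted p = 0.550 with an estimated correlation), 27 past the threshold adjusted over the list alone. Rps19 was 1.75-fold higher, Rplp0 1.77-fold, Rpl32 1.72-fold and Rps9 1.63-fold; these genes have pseudogene copies that can share reads. Extracellular matrix and fibrosis genes had a median of 0.83 over 32 members (adjusted p = 3.20e-06; adjusted p = 0.550 with an estimated correlation), 0.37 without knockout replicate 2, and all 32 log2 fold changes were above 0. The 4 past the threshold adjusted over the list alone were Timp1, Col18a1 (2.06-fold higher), Lama5 (2.19-fold), a laminin chain of the glomerular basement membrane, and Col6a3 (3.12-fold). Actin cytoskeleton and focal adhesion genes had a median of 0.54 over 30 members (adjusted p = 3.06e-05; adjusted p = 0.550 with an estimated correlation), with 16 higher and 1 lower past the threshold adjusted over the list alone. The integrin gene Itgav was 2.34-fold higher, the myosin gene Myh9 2.55-fold, Actn1 2.69-fold and Cfl1 1.75-fold.

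The lists closest to HDAC function did not pass with log2(TPM + 1). The class I, II and IV HDAC genes had a median of 0.13 over 10 members (camera adjusted p = 0.228), or -0.08 without control replicate 2, with log2 fold changes of 0.51 (SE 0.15) for Hdac6, 0.61 (SE 0.31) for Hdac7, 0.38 (SE 0.20) for Hdac5 and 0.31 (SE 0.17) for Hdac3. Genes of the HDAC1 and HDAC2 complexes had a median of 0.17 over 29 members (adjusted p = 0.0962), or 0.10 without knockout replicate 2, and passed with a pseudocount of 5 (0.0330) and by voom (0.0207), in a range from 0.0207 to 0.474 over the settings tried. Of its members, Elmsan1 was 2.00-fold higher, Rest 1.51-fold, Mbd2 1.43-fold and Chd4 1.40-fold. Neuronal genes repressed through REST, of which 9 were tested, had a median of 0.04 (adjusted p = 0.722), which lay between -0.14 and -0.01 as each library was left out; Uchl1 (2.48-fold higher) and Cplx2 (1.90-fold higher) were past the threshold adjusted over the list alone, and the log2 fold change of Syp was -0.51 (SE 0.31). Of the germline genes only Sycp1 (0.883 and 0.999 TPM in the controls, 1.02 and 1.58 TPM in the knockout-labelled libraries) and Sycp3 (1.89, 3.26, 2.43 and 2.46 TPM in the same order) reached the filter, and they were not tested as a list; 52.2% of the exon bases of Sycp3 lie in an antisense gene. Linker and polyadenylated histone genes had a median of 0.11 over 14 members (adjusted p = 0.198), or 0.27 without control replicate 1 and 0.00 without control replicate 2. H3f3b was 1.79-fold higher, Hist1h1c 1.64-fold, H2afz 1.51-fold and H2afy2 1.69-fold, and 4 members passed adjusted over the list alone. For these 5 lists the camera adjusted p with an estimated correlation was between 0.550 and 0.774 where it was computed.

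Erythroid genes, a sign of blood in a preparation, did not pass (median -1.11 over 5 members, camera adjusted p = 0.137), but did without knockout replicate 2 (0.00105, median -2.26). The median was -1.68 without control replicate 1, -0.42 without control replicate 2 and -0.03 without knockout replicate 1. Hbb-bs was at 18.9 and 72.8 TPM in the controls and 7.27 and 40.9 TPM in the knockout-labelled libraries, Hbb-bt at 3.40, 13.0, 0.795 and 5.10 TPM and Hba-a1 at 11.6, 32.2, 3.10 and 26.8 TPM; these globin genes have near-identical copies. Slc25a37 was at 12.4 ± 1.64 and 13.3 ± 1.11 TPM. Sex-linked genes did not pass (median 0.64, mean -0.26 relative to the mean of all genes, adjusted p = 0.525), but did without control replicate 1 (0.0395), and the median was -0.21 without control replicate 2. Xist, which is transcribed from the inactive X chromosome, was at 0.10, 173, 0.11 and 0.13 TPM in control replicates 1 and 2 and knockout replicates 1 and 2. Y-linked Eif2s3y was at 24.4, 8.09, 27.5 and 27.1 TPM, Ddx3y at 23.6, 8.45, 25.1 and 26.1 TPM, Kdm5d at 7.89, 2.66, 9.04 and 9.27 TPM and Uty at 10.2, 3.40, 12.3 and 9.88 TPM. Control replicate 2 was the 1 library with Xist above 1 TPM.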

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

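The settings with voom and the adjusted p under 0.1 were chosen after seeing the data. The count of genes higher, 0 in the limma test, was 1529 by voom with the replicate block and 130 at an adjusted p under 0.1. The count lower, 1, was 0 with quantile normalization, with limma without trend, by voom on the recovered reads and by voom with median-ratio factors, 632 by voom with the replicate block and 46 at an adjusted p under 0.1. As each library was left out the counts ranged from 0 to 1558 and from 0 to 522, the highest without control replicate 2. The number of lists past the threshold, 22, was 0 with an estimated correlation and 0 by fry, 20 to 22 as each library was left out, and 19 to 23 in the other settings. The podocyte list had an adjusted p of 0.550 with an estimated correlation and 0.660 by fry, and between 4.63e-12 and 0.00105 as each library was left out. Hdac2 reversed to -0.22 with median-ratio scaling, -0.17 with quantile normalization, -0.044 by voom, -0.23 by voom with median-ratio factors and -0.044 by voom with the replicate block, and ranged from -0.12 to 0.13 as each library was left out. Slc25a37 reversed to -0.11 with median-ratio scaling, -0.11 with quantile normalization and -0.12 by voom with median-ratio factors, and Sycp1 to -0.024 with quantile normalization. As each library was left out, Slc25a37 ranged from -0.020 to 0.23, Sycp3 from -0.30 to 0.25, mt-Atp6 from -0.77 to 0.052, mt-Atp8 from -0.43 to 1.16, Hbb-bs from -2.21 to 0.13 and Hba-a1 from -2.32 to 0.44. The cause was not tested. Of 434 list results under other fits, 413 kept their side of the threshold, 14 were no longer past it and 7 came past it. Of the 22 lists past the threshold, 0 changed camera's direction. The median of the glomerular endothelial list, relative to all genes, still turned to 0.07 without control replicate 2. Of the other lists, the sex-linked list turned downward without control replicate 2 and the mesangial list upward without knockout replicate 1. Of 2006 values of the 135 named genes other than Hdac1 and Hdac2, 1995 kept their direction. With the replicate block limma called 0 genes higher and 1 lower, and the differences between replicates correlated by 0.14 across genes between the groups. The planned count models were not run.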

Other observations

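All tests of explanations here were chosen only after the result was seen. Genes and gene families in this paragraph were chosen after their values were seen. Among 62 families of gene symbols with at least 20 tested members, 8 passed camera upward and 6 downward, and 0 passed with an estimated correlation (lowest adjusted p = 0.942). Histone genes whose symbols start with Hist had a median log2 fold change of 1.28 over 55 members, 47 of them above 0 (adjusted p = 1.2e-10), or 1.10 after median-ratio scaling. The fixed list of linker and polyadenylated histone genes was at 0.28 as deposited over 14 members, or 0.05 after median-ratio scaling, and did not pass. The libraries were made from poly(A) RNA, and whether more Hist transcripts carried a poly(A) tail was not tested. The fibrinogen genes, which the liver expresses, were higher in both knockout-labelled libraries. Fga was at 11.6 and 67.0 TPM in the controls and 713 and 478 TPM in the knockout-labelled libraries, and Fgg at 5.36, 68.6, 715 and 441 TPM. The MHC class I genes H2-K1 and H2-D1 were 4.59-fold and 4.01-fold higher, and B2m, their light chain, 2.98-fold. The slit diaphragm gene Nphs1 was at 15.3 and 34.7 TPM in the controls and 1.48 and 8.43 TPM in the knockout-labelled libraries. Control replicate 1 stood apart in some proximal tubule genes, with Kap at 31062 TPM against 987, 1004 and 1202 TPM in control replicate 2 and knockout replicates 1 and 2, and Slc7a13 at 512 against 6.81, 5.02 and 5.64 TPM. Lrp2 and Slc22a8 differed less between the controls, at 1453 and 997 TPM and at 267 and 346 TPM in control replicates 1 and 2. The cause was not tested.

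Immune cell, parietal epithelial and kidney injury genes were higher in the knockout-labelled libraries. A lower proximal tubule share would raise the genes of all other cell types alike, but the immune cell median exceeded the endothelial one by 2.56 (two-sided permutation p = 1e-05 over genes, the smallest 100000 permutations can give, n = 18 and 22). The parietal median exceeded the endothelial one by 1.59 and the injury median by 3.20. Genes of the same pools move together, so the permutation p does not measure the spread between pools. As the cause of this pattern, female mice in control replicate 2 are argued against by the medians without that library. The immune cell median was then 3.11 as deposited, or 2.78 relative to all genes. The relative medians were 1.45 for the parietal and 3.26 for the injury list. Control replicate 1 is then the only control, and it stood apart in some proximal tubule genes such as Kap, so the argument rests on that library alone. A change in the cells themselves, or more immune cells in the knockout-labelled pools, stays open and may follow from the deletion, which was not tested.

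Kidney injury genes of control replicate 2 lay between control replicate 1 and the knockout-labelled libraries, with Havcr1 at 0.711, 53.7, 365 and 450 TPM and C3 at 4.97, 261, 2887 and 2480 TPM in the order control 1, control 2, knockout 1 and knockout 2. The mixing of RNA was read on 32 genes with a mean in the knockout-labelled libraries at least 20 times the value in control replicate 1. That mean also had to reach 20 TPM, and the 2 knockout-labelled values had to differ by less than 1.5-fold. The 1.5-fold limit left out genes such as Lcn2, at 1.77, 25.5, 562 and 339 TPM in the same order, and Krt19, at 2.01, 3.13, 67.2 and 26.9 TPM. Over the 32 genes kept, control replicate 2 lay from 5.72% (Cd14) to 34.7% (Ankrd1) of the way. Against RNA of the 2 knockout-labelled libraries mixed in at 1 share as the whole cause, the best share lay outside the 99.9% counting limits of 5 genes, if the library's own level was 0 to 2 times that of control replicate 1, and of 3 genes at 0 to 4 times; C3 allowed at most 10.9% and Vcam1 at least 18.3%. With RNA of another knockout pool, within 1.5 times of these libraries, 0 genes lay outside, so that source cannot be told apart from a milder change in the pool. Female mice in control replicate 2 cannot be told apart from the library itself, since it was the 1 library with Xist above 1 TPM.

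Podocyte genes were lower in the knockout-labelled libraries. Fewer glomeruli would lower podocyte and endothelial genes alike. Members that track glomerular content were taken as those higher by at least 0.5 log2 units in replicate 2 of both groups. For these, the podocyte median was below the endothelial one by 0.52 (-0.76 against -0.24, difference -0.52, two-sided permutation p = 0.00373 over genes, n = 20 and 18). The difference was -0.69 to -0.48 as each library was left out, with the members still chosen from all 4 libraries. The rule does not single out glomerular content. Erythroid genes were also higher in replicate 2, by medians of 1.40 log2 units in the controls and 1.77 in the knockout-labelled libraries. Genes of the same pools move together, so the permutation p does not measure the spread between pools. The gap argues against an equal fall of both sets, but not against fewer glomeruli. That would need all endothelial members to measure glomeruli, and Ehd3, a glomerular endothelial marker, was itself at -0.90. For all members the difference was -0.29 (permutation p = 0.0908, n = 36 and 22). It was -0.048 without control replicate 1, -0.092 without knockout replicate 2, -0.37 without knockout replicate 1 and -0.61 without control replicate 2. With all 4 libraries the medians did not separate past the threshold, so fewer glomeruli cannot be told apart there from a change in podocytes. Lower transcript levels in podocytes, fewer podocytes or fewer glomeruli may underlie the lower podocyte genes, and these 4 pooled libraries do not separate them.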
